A study of Mus musculus with 24 samples.

How the data were processed

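Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed in 14 libraries of C57BL/6 mouse cells, each with 1 deposited peak list. The series held 24 samples. The other 10 were input libraries, sonicated DNA without an antibody, for which no file was used here. The cells were induced hepatocyte-like (iHep) cells, made from mouse embryonic fibroblasts of embryonic day 13.5, and hepatocytes isolated from livers of 10-week-old adult mice. Per the labels, line 4a1 was infected with Foxa1 and Hnf4a, line 4a2 with Foxa2 and Hnf4a, and line 4a3 with Foxa3 and Hnf4a. Foxa1, Foxa2 and Foxa3 are forkhead transcription factors that bind DNA in liver and other endodermal tissues. Hnf4a is a nuclear receptor of hepatocytes. Libraries that the series' design text names for Hnf4a, and for cells at an earlier stage of conversion, were not analysed here.

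Per the submitters' processing notes, the tools were BWA 0.6.2, MACS2 2.1.0 and bedtools 2.16.2, and the genome build was mm9. The notes used here give no role, order or setting for these tools. Each file is tied to 1 library, so lists were treated as called per library. Whether an input was subtracted, and the calling threshold, are not given in the sources used here. Each line of a deposited list gives a chromosome, a start, an end, a peak name and a score. The score is the authors' own value for the peak, on a scale not given in the sources used here. In the Flag list of line 4a3 the lowest score was 50.0, against lowest scores just above 5 in the other lists, so that list is on another scale or threshold. Scores were therefore used only to rank peaks within a list. The narrowest peak was 317 bp in the non-EGS list of line 4a1 and 320 bp in that of line 4a2, and between 57 and 127 bp in the other lists. Why the narrowest peaks differ in width is not known.

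Library depth is unknown, since the files hold no read counts. The length of a list is not a depth. Intervals on shares are exact 95% Clopper-Pearson intervals over peaks. They cover counting error only, and they are too narrow where peaks of a list lie close together, since such peaks are not independent. Replicates are libraries with different culture numbers in their titles. The labels do not say that these are separate inductions, so p-values across libraries measure the spread between these samples, which may be technical. EGS, a term in some titles, is not spelled out in the labels and served only as a label. Most titles also carry a run code, which was treated as a possible batch. The non-EGS library of line 4a3 has none.

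Coordinates are those of the files (mm9), with starts written 1-based. The annotation at hand was of build GRCm38.p6. A total of 190 peaks lay beyond the last gene of that table on their chromosome, 97 of them on chromosome 7, so the builds were not interchangeable and no gene was assigned to any peak. The planned analyses of fixed gene lists, of positions relative to genes, of the introduced genes and of the forkhead motif need mm9 annotation or sequence and were not analysed here.

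Lists were compared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp. Chance overlap came from 1000 circular shifts of the shorter list along each chromosome, which keep widths and spacing. The highest peak end over all lists stood for the chromosome's length. The test is one-sided, and 0.001 is the smallest p it can give. Over the 91 pairs of lists, p was adjusted by Benjamini-Hochberg. Similarity of a pair was log2 of observed over expected shared peaks, with 0.5 added to each. Differences across libraries were tested by exact permutation: peak counts on the log10 scale over the 84 assignments of 3 non-EGS and 6 EGS iHep libraries (two-sided), and similarity within against between lines over the 280 ways to form 3 lines of 3 (one-sided). A second version relabelled lines separately within EGS and within non-EGS libraries. Merged regions are unions of overlapping peaks.

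Regions to be named were fixed by rule. For each set of sites, the 5 merged regions found in most of the 12 Foxa libraries were taken, with ties broken by the mean percentile of the score within its list. The rule did not say which libraries count for sites of a single line. As first coded, those of that line were counted. A version that counted all 12 Foxa libraries was then looked at. It put regions of the dense block on chromosome 9 first for line 4a1, and regions that hepatocyte lists also hold first for the other lines. The first version was restored, so this choice was made with both outcomes known. Alternatives fixed before the data were examined were the top-scoring 50% of each list, an overlap of at least 50% of the narrower peak, and the top 300 peaks of each list. Also fixed were leaving out 19 regions that recur in lists of all kinds, covered length, merging within 1 kb, the Jaccard index, restriction to EGS or non-EGS libraries, blocks, and leaving out each library. No list held unplaced contigs or the mitochondrial genome.

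After the data were seen, dense runs were added: chains of at least 4 peaks in 1 list with no gap above 10 kb. A dense block is a region with such a run in at least 2 of the 3 hepatocyte lists. There were 4 blocks, and leaving them out was added as an alternative. The settings for the share of one line's regions in another, leaving out each library for the mean similarity of pairs, and thinning each list to 500 random peaks (mean of 100 draws, shorter lists whole, with and without the list of 46 peaks) were also added then. The tests of technical explanations were all written after their results were seen, and 4 of them were changed after a first outcome. The test of list length for the Flag list of line 4a3 first set the lowest count of the other lines against the highest of its own line, which left the question open. It was replaced by paired exact tests within EGS and within non-EGS lists. The test of the sequencing run for the block on chromosome 9 was made stricter, to need lists of at least 100 peaks, which turned its outcome from against the explanation to open. The test of the sequencing run for the dense runs first left out the blocks, which are defined from some of the lists it compares. It was moved to all peaks, which turned its outcome from against the explanation to open. It was then split by run code, with the Flag lists added and at least 100 peaks per list needed to exclude the run. This turned its outcome against the explanation for Foxa3 EGS replicate 1 and left it open for the other lists. The test of merged peaks first used the lowest and highest lists and then the difference in means, with the same outcome.

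The shift test was tested on simulated lists with the real lengths and widths, placed at random positions. Such lists lack the clustering of the real ones: dense runs held 0.035% of the peaks of the longest simulated list. The error rates therefore do not show how the test behaves on clustered lists. Of 364 pairs of independent lists, 1.10% had p below 0.05, and 4.17% of the 48 pairs with at least 1 shared peak expected. With 10% of the shorter list planted in the longer, p fell below 0.05 in 100% of 91 pairs. The run finder recovered 100% of 40 planted runs.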

Results

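The binding sites of 3 Foxa proteins were mapped in iHep cells and in adult hepatocytes. Line 4a1 was profiled with a Foxa1 antibody, line 4a2 with a Foxa2 antibody and line 4a3 with a Foxa3 antibody, in 3 libraries each. Of the 3, 2 carry EGS in their title and 1 does not (non-EGS). A Flag antibody, which recognises an epitope tag, was used once in line 4a2 and once in line 4a3. The labels do not say which protein carries the tag. Hepatocytes gave 1 EGS library for each Foxa antibody, all from preparation 4, so differences between hepatocyte antibodies have no replicate check. In iHep cells the line, the introduced factor and the antibody change together and cannot be told apart. The 14 lists held 26332 peaks, which merged into 18022 regions. Of these, 13614 were found in 1 list only. The depth of the libraries is unknown.

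The first question was how many sites each library gave, since this bounds every overlap. The longest list was Foxa2 in line 4a2 without EGS, with 11408 peaks over 5473 kb. The non-EGS lists of lines 4a3 and 4a1 held 4317 and 3431 peaks. The EGS lists were shorter, with 940 and 542 peaks for Foxa1, 957 and 1040 for Foxa2, and 1246 and 46 for Foxa3. The geometric mean was 5528 peaks in the 3 non-EGS libraries and 554 in the 6 EGS libraries, a ratio of 9.97 (exact permutation test, two-sided, p = 0.024, the smallest that 84 assignments allow). The SD of log10 counts was 0.28 (n = 3) and 0.54 (n = 6). All 3 non-EGS lists were longer than all 6 EGS lists.

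The ratio was 6.06 without replicate 3 of the Foxa3 EGS libraries and 22.3 for covered length, since non-EGS peaks were also wider (median 180 to 458 bp, against 135.5 to 149 bp). No run code holds iHep Foxa libraries of both kinds, so EGS and run cannot be told apart. Permuting within lines gave an exact p of 0.074, the smallest that 27 assignments allow. The Flag lists held 21 peaks (line 4a2) and 883 peaks (line 4a3). The hepatocyte lists held 166 peaks for Foxa1, 244 for Foxa2 and 1091 for Foxa3.

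**Figure D1:**
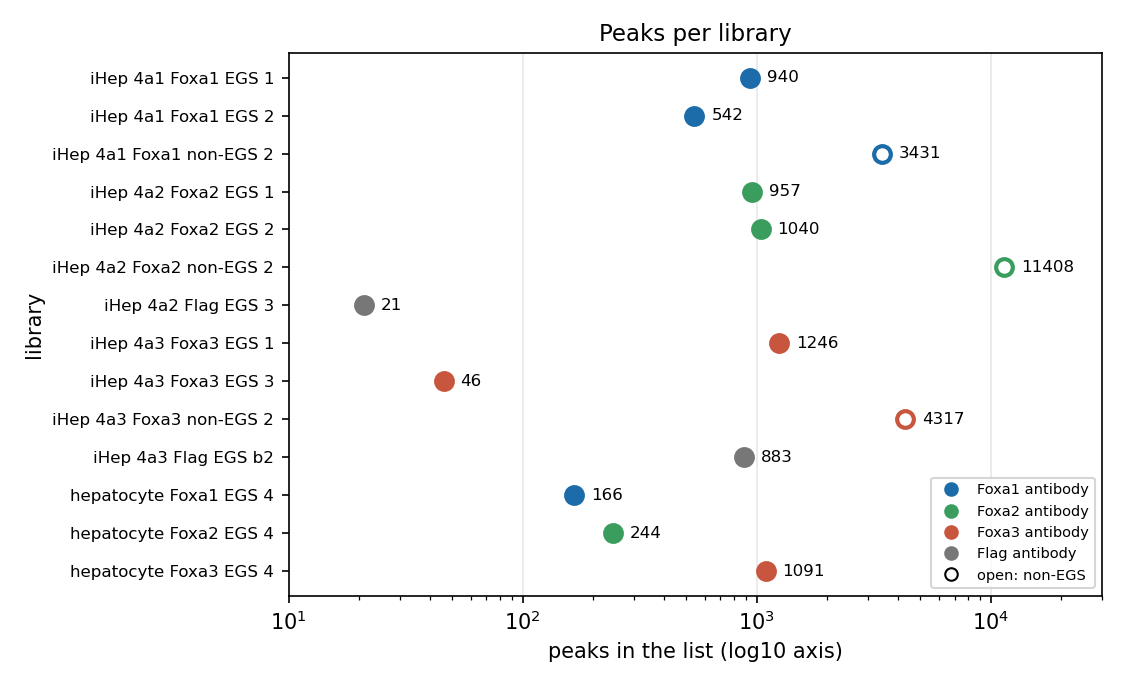
Number of peaks in each of the 14 lists, on a log10 axis, 1 point per library, coloured by antibody; open points are non-EGS libraries. The 3 non-EGS lists (3431, 4317 and 11408 peaks) lie above all 6 EGS lists of iHep Foxa libraries (46 to 1246).

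The share of EGS sites found in the longer list of the same line differed between libraries. In line 4a2, 82.7% (95% interval 80.3 to 84.9) of the 1040 EGS peaks of culture 2 overlapped a non-EGS peak of the same culture number. Of the 957 EGS peaks of culture 1, 87.6% (85.3 to 89.6) overlapped one of that culture 2 list. In line 4a1 the share for culture 2 was 58.5% (54.2 to 62.7), and 70.2% (65.8 to 74.4) without the 4 dense blocks. For culture 1 it was 61.6% (58.4 to 64.7). For Foxa3 it was 51.0% (48.1 to 53.8) for replicate 1 and 93.5% (82.1 to 98.6) for the 46 peaks of replicate 3, both against a culture with another number. Shifted lists gave under 1% in each case (circular-shift permutation p = 0.001, the smallest that 1000 shifts give).

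The second comparison asked whether the lines occupied the same sites. Foxa1 sites were found among Foxa2 sites more often than among Foxa3 sites. Of the 3969 merged regions of line 4a1, 71.3% (69.8 to 72.7) overlapped a region of line 4a2, and 10.9% (9.98 to 11.9) a region of line 4a3. Of the 11677 regions of line 4a2, the longest set, 24.1% (23.4 to 24.9) overlapped line 4a1 and 6.62% (6.18 to 7.09) line 4a3. Of the 4915 regions of line 4a3, 9.0% (8.21 to 9.83) overlapped line 4a1 and 16.8% (15.8 to 17.9) line 4a2. Chance gave 0.4% or less in each (permutation p = 0.001). With EGS libraries only, 47.2% (44.3 to 49.99) of the 1230 regions of line 4a1 overlapped line 4a2, and 14.1% (12.2 to 16.1) overlapped line 4a3. These shares moved with the non-EGS libraries. Without that of line 4a2, the shares were 19.6% of 4a1 in 4a2, 8.59% of 4a3 in 4a2, and 50.1% and 26.8% of 4a2 in 4a1 and 4a3. Without that of line 4a1 they were 27.1% of 4a1 in 4a3 and 8.55% of 4a2 in 4a1, and without that of line 4a3 they were 5.24% and 2.39% of 4a1 and 4a2 in 4a3 and 16.5% of 4a3 in 4a1. With the top 300 peaks, 37.1% of 4a1 regions were in 4a2 and 7.28% in 4a3. The 940 Foxa1 peaks of EGS replicate 1 overlapped the Foxa2 non-EGS list in 90.7% of cases, more than the 61.6% (58.4 to 64.7) in the Foxa1 non-EGS list, which is shorter.

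Averaged over pairs of libraries, the log2 observed/expected overlap was 8.09 ± 1.10 (SD, 9 pairs) within lines and 6.21 ± 2.71 (SD, 27 pairs) between lines. The difference of 1.88 gave p = 0.0036 in the exact permutation test (one-sided), the smallest that 280 labelings allow. It gave an exact p of 0.011, again the smallest possible, when lines were relabelled within EGS and non-EGS libraries. The contrast came from line 4a3. Pairs of a 4a1 with a 4a2 library reached 8.27 ± 0.65 (SD, 9 pairs), near the 8.68 ± 0.21 within 4a1 and the 8.48 ± 0.82 within 4a2 (SD, 3 pairs each). Pairs with a 4a3 library reached 5.18 ± 2.79 for 4a1 and 5.17 ± 2.92 for 4a2 (SD, 9 pairs each). Within line 4a3 the value was 7.10 ± 1.39 (SD, 3 pairs). Without the Foxa3 list of 46 peaks these were 6.99 ± 0.77 and 7.03 ± 1.06 (SD, 6 pairs each), and 8.71 for the 1 pair left within 4a3.

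The difference was 1.05 (exact p = 0.0036) without replicate 3 of the Foxa3 EGS libraries, the list of 46 peaks. On the Jaccard index in bp the difference was 0.026 and no longer passed the threshold (exact p = 0.096), and with EGS libraries alone the smallest possible exact p is 0.067. Pairs of 4a1 and 4a2 libraries with the same run code reached 9.23 (2 pairs), against 7.995 for the other 7, of which 5 include a non-EGS list and the 2 pairs of EGS lists reached 8.31. With small expected counts these values also follow list length. The shorter list held 940 peaks in the pairs with the same run code and 542 in the other EGS pairs. The shares of the shorter list were 41.3% and 39.3%, against 32.7% and 34.9%, so run and list length cannot be told apart here. The 1 pair of a 4a3 library with the same run code, which uses the list of 46 peaks, reached 1.58, against 5.39 for the other 17 pairs with 4a1 or 4a2. Without all pairs that share a run code the difference was 1.77 (exact p = 0.0036).

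**Figure D2:**
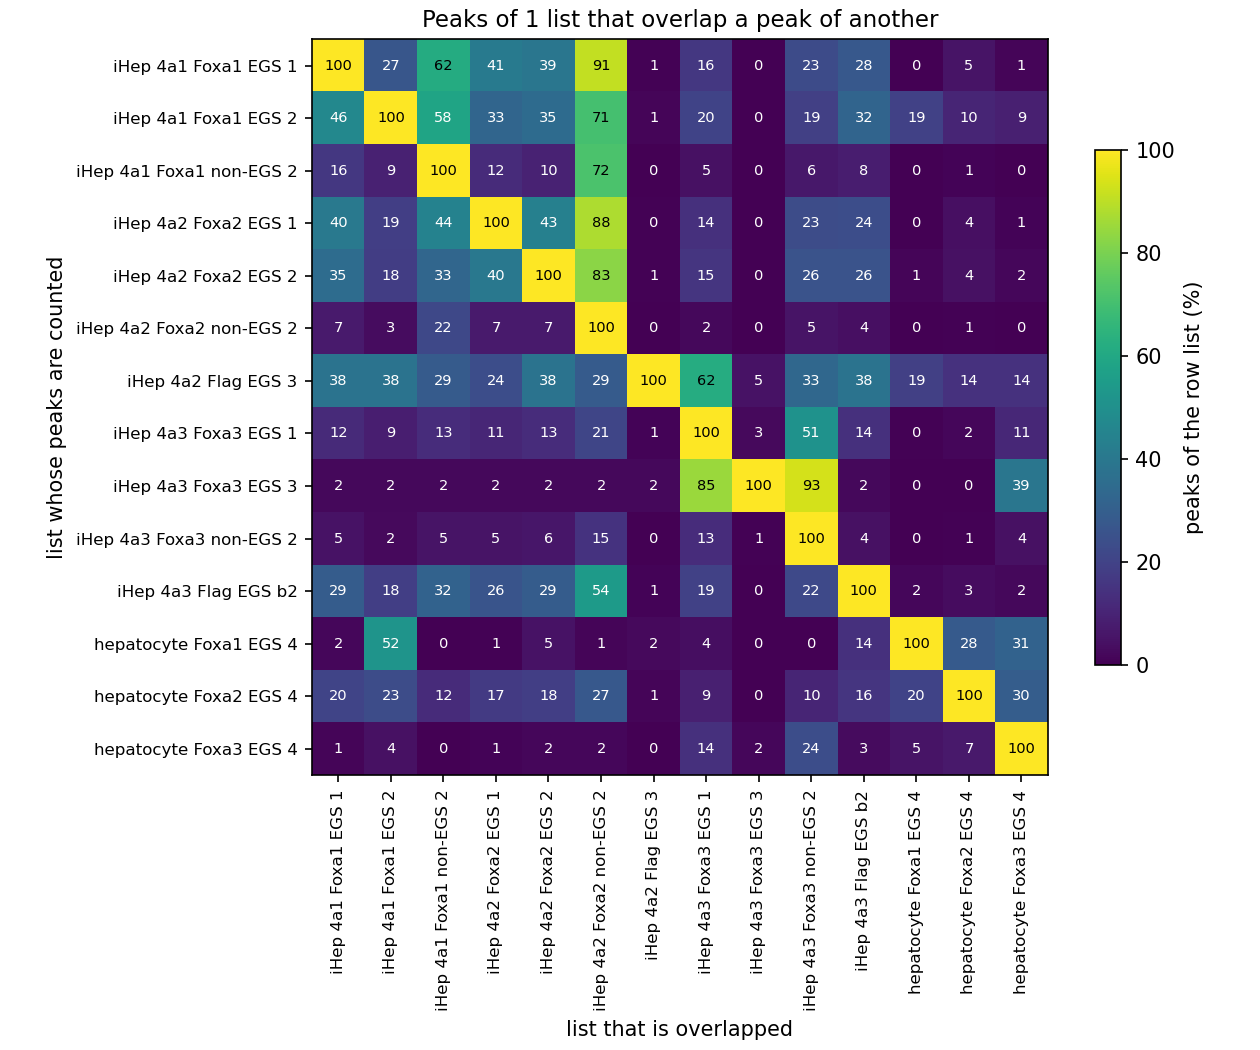
Percent of the peaks of each list (rows) that overlap a peak of each other list (columns) by at least 1 bp. Foxa1 and Foxa2 lists of iHep cells fill the upper left corner, with 90.7% of Foxa1 EGS 1 peaks in the Foxa2 non-EGS list. The Foxa3 lists overlap one another and the hepatocyte Foxa3 list.

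Sharing rose with the rank of a peak for Foxa1 and Foxa2 but not for Foxa3. In the top decile of the Foxa2 non-EGS list by score, 72.2% (69.5 to 74.8) of 1141 peaks were also Foxa1 non-EGS peaks. In the bottom decile the share was 4.82% (3.65 to 6.23). In the Foxa1 non-EGS list, 93.3% (90.1 to 95.7) of the top decile and 56.0% (50.5 to 61.3) of the bottom decile were Foxa2 non-EGS peaks. In the Foxa3 non-EGS list the share in the Foxa2 non-EGS list was 12.7% (9.74 to 16.2) in the top decile and 11.4% (8.53 to 14.8) in the bottom decile.

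Against chance, 85 of the 91 pairs of lists shared more peaks than shifted lists (adjusted p below 0.05). Some of the 85 shared only 1 peak. The list of 46 peaks did so with each Foxa1 and Foxa2 EGS list of iHep cells and with both Flag lists. The 6 pairs that did not pass all involved the hepatocyte Foxa1 list (4 pairs) or the list of 46 peaks (3 pairs), with 1 pair holding both. The hepatocyte Foxa1 list shared 0 of its 166 peaks with the iHep Foxa1 non-EGS list, which allows a share of up to 2.20% by the exact interval.

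The third question was which sites all 3 lines had in common. Of 16880 merged regions in the 9 iHep Foxa libraries, 418 held a peak in each line, and 57 held one in at least 2 libraries of each line. By lines, 8506 regions were found in 4a2 alone, 4070 in 4a3 alone and 1120 in 4a1 alone. A further 2395 were in 4a1 and 4a2, 351 in 4a2 and 4a3, and 20 in 4a1 and 4a3. Counted on the regions of line 4a3, 422 overlapped both other lines, against a mean of 3.53 after shifting (permutation p = 0.001). The count of common regions fell to 191 without the Foxa3 non-EGS library. It was 130 with EGS libraries only, 218 with non-EGS libraries only, 178 with the top-scoring 50% of each list and 37 with the top 300 peaks.

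One region, on chromosome 17 from 35848274 to 35849145 (mm9), held a peak in all 9 iHep Foxa lists and in both Flag lists, at a mean score percentile of 98.3, and in no hepatocyte list. A further 27 regions were found in 8 of the 9. The region on chromosome 8 from 96910402 to 96911889 was found in most Foxa libraries, 8 of iHep cells and 2 of hepatocytes. Those on chromosome 10 (86306948 to 86309767), chromosome 4 (137423070 to 137423720) and chromosome 16 (30603031 to 30603638) followed, each in 8 iHep lists and 1 hepatocyte list.

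Sites of a single line, defined by the iHep Foxa lists without the Flag lists, were led by other regions. For line 4a3 they lay on chromosome 13 (23830434 to 23832145), on chromosome 11 (69571649 to 69572490, 101506278 to 101507869 and 101519137 to 101519572) and on chromosome 12 (55810556 to 55812270). All 5 held a peak in all 3 Foxa3 libraries of iHep cells, with mean score percentiles of 94.0 to 97.7. The 4 regions on chromosomes 11 and 12 were also in the hepatocyte Foxa3 list. For line 4a2 they lay on chromosome 18 (82691909 to 82692761 and 39643100 to 39643535), chromosome 15 (79198606 to 79199466) and chromosome 2 (78301334 to 78301847 and 157939505 to 157939958), each in all 3 libraries. For line 4a1, 2 regions were in all 3 libraries, on chromosome 11 (64640971 to 64641549) and chromosome 12 (100445113 to 100445722). That on chromosome 11 also held a peak of 1 Flag list, which comes from another line. The other 3 were in 2 libraries, on chromosome 16 (62418470 to 62418950), chromosome 15 (41677498 to 41678012) and chromosome 4 (33957891 to 33958513).

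In hepatocytes the 3 antibodies gave largely different lists. Of the 166 Foxa1 peaks, 28.3% (21.6 to 35.8) overlapped a Foxa2 peak and 31.3% (24.4 to 39.0) a Foxa3 peak. Of the 244 Foxa2 peaks, 29.5% (23.9 to 35.7) overlapped a Foxa3 peak. All were above chance (permutation p = 0.001). Of 1359 merged hepatocyte regions, 39 were in all 3 lists. Most of this overlap lay in the 4 dense blocks, on chromosome 9 (3000010 to 3038304), chromosome 10 (7229710 to 7237012), chromosome 11 (3041272 to 3100001) and chromosome 17 (39980018 to 39985706). The blocks held 52.4% of the Foxa1 list, 29.9% of the Foxa2 list and 9.72% of the Foxa3 list. The blocks are defined by runs that these lists share, so leaving them out lowers the overlap in part by construction. Without them the shares were 6.33%, 10.1% and 8.19%, still above chance (permutation p = 0.001), and 4 regions were in all 3 lists. With the top-scoring 50% of each list they were 2.41%, 3.61% and 8.20%. With the top 300 peaks the Foxa1 and Foxa2 shares in the Foxa3 list were 4.22% and 10.7%.

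The fourth comparison asked how much of the hepatocyte binding was found in iHep cells. Of the merged hepatocyte regions, 34.2% (31.7 to 36.8) overlapped an iHep Foxa peak of any line, against 0.41% by chance (permutation p = 0.001). The share was 22.1% with EGS libraries alone. Hepatocyte Foxa3 peaks were found most often in line 4a3, where Foxa3 was introduced and the Foxa3 antibody was used. Factor and antibody cannot be told apart here. Of the 1091 peaks, 25.8% (23.2 to 28.5) were in line 4a3, against 5.59% (4.30 to 7.12) in line 4a1. In line 4a2 it was 3.67% (2.63 to 4.96), although line 4a2 had the longest list. The share in line 4a3 was 13.9% without its non-EGS library. Of the 244 hepatocyte Foxa2 peaks, 34.8% (28.9 to 41.2) were in line 4a2, 40.2% (34.0 to 46.6) in line 4a1 and 13.9% (9.85 to 18.9) in line 4a3. Without the blocks they were 46.8% (39.1 to 54.6), 34.5% (27.4 to 42.1) and 18.7% (13.2 to 25.4). The share in line 4a2 was 22.5% without its non-EGS library and 14.8% with the top 300 peaks.

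Of the 166 hepatocyte Foxa1 peaks, 52.4% (44.5 to 60.2) were in line 4a1. This rested on 1 library: the share was 1.81% without EGS replicate 2 of line 4a1, 19.0% (11.03 to 29.4) without the blocks and 86.7% with the top-scoring 50% of each list. The sites common to hepatocytes and iHep cells were led by the regions on chromosomes 8, 10, 4 and 16 named above and by chromosome 16 from 90779927 to 90780602, in 8 iHep lists and 1 hepatocyte list. The 5 leading hepatocyte-only regions all lay in the block on chromosome 10, between 7231865 and 7236610, in all 3 hepatocyte lists. These regions held no iHep Foxa peak, but Flag lists were not counted for this set. All of them except 7231865 to 7232065 also held a peak of 1 Flag list of iHep cells. After the region on chromosome 17, the leading iHep-only regions were on chromosome 18 (70259381 to 70260075), chromosome 13 (41447595 to 41448154), chromosome 1 (51565256 to 51565810) and chromosome 9 (62938644 to 62939616), each in 8 iHep lists.

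The Flag list of line 4a3 did not follow the line it came from, and that of line 4a2 left this open. Of the 883 Flag peaks of line 4a3, 58.2% (54.9 to 61.5) overlapped a Foxa2 peak of line 4a2 and 42.2% (39.0 to 45.6) a Foxa1 peak of line 4a1. In its own line, 31.8% (28.8 to 35.01) overlapped a Foxa3 peak. With the top 300 peaks of each list these were 42.7%, 42.7% and 19.0%. All were above chance (permutation p = 0.001). On the log2 observed/expected scale the lists were closer together, but with small expected counts this scale also follows list length. The log2 observed/expected overlap of the Flag list was 7.98 and 7.18 with Foxa3 EGS replicate 1 and Foxa3 non-EGS, 1.53 with Foxa3 EGS replicate 3, and 7.08 to 8.60 with the 6 lists of the other lines. Of the 21 Flag peaks of line 4a2, 15 overlapped a Foxa3 peak of line 4a3 (71.4%, 47.8 to 88.7), and 9 each overlapped lines 4a1 and 4a2 (42.9%, 21.8 to 66.0). These intervals overlap, but they ignore that the same 21 peaks are compared. No paired test was run for this list.

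In iHep cells, peaks of the Foxa3 lists lay close together. Dense runs held 27.4%, 32.6% and 30.4% of the peaks in the 3 Foxa3 lists of iHep cells (mean 30.1% ± 2.63, SD, n = 3). In the 6 Foxa1 and Foxa2 lists they held between 0% and 17.7% (mean 3.55% ± 6.98, SD, n = 6). The difference of 26.6 percentage points gave p = 0.024 in the exact permutation test (two-sided), the smallest that 84 assignments allow. It fell to 2.85 (exact p = 0.17) when peaks within 1 kb were merged, and to 8.37 (exact p = 0.19) with the top 300 peaks. With each list thinned at random to 500 peaks it was 13.003 (exact p = 0.19), and 16.02 (exact p = 0.024) without the blocks. Dense runs of the thinned lists held 14.2% of Foxa3 EGS replicate 1 and 1.45% of the Foxa3 non-EGS list, while the list of 46 peaks, too short to thin, kept its 32.6%. Without that list the thinned difference was 4.74 (exact p = 0.57), and 7.83 without the blocks (exact p = 0.071, the smallest possible). Without the blocks the 6 Foxa1 and Foxa2 lists reached at most 2.07%. In hepatocytes, dense runs held 60.5% (57.5 to 63.4) of 1091 Foxa3 peaks, 54.8% (46.9 to 62.5) of 166 Foxa1 peaks and 29.9% (24.2 to 36.1) of 244 Foxa2 peaks. The intervals of the Foxa3 and Foxa1 lists overlapped. Peaks of 1 run are not independent, so these intervals are too narrow: the dense runs numbered 67, 4 and 5. Without the blocks, which are defined by runs that these lists share and so take such runs out by construction, they held 56.2% of 985 Foxa3 peaks, 5.06% of 79 Foxa1 peaks and 0% of 171 Foxa2 peaks.

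The run with most peaks in the Foxa3 non-EGS list spanned 56.3 kb on chromosome 19 (5794052 to 5850312) with 35 peaks. The same interval held 29, 17 and 13 peaks in the Foxa3 EGS replicates 1 and 3 and the hepatocyte Foxa3 list, and at most 2 in any other list. In hepatocytes the run with most peaks outside the blocks spanned 22.7 kb on chromosome 4 (150226804 to 150249468), with 38 Foxa3 peaks. It held 4 peaks of the iHep Foxa3 non-EGS list, 2 of Foxa3 EGS replicate 1 and none of the other 11 lists. These runs were chosen after their values were seen. Whether they follow transcribed genes was not analysed here.

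**Figure D3:**
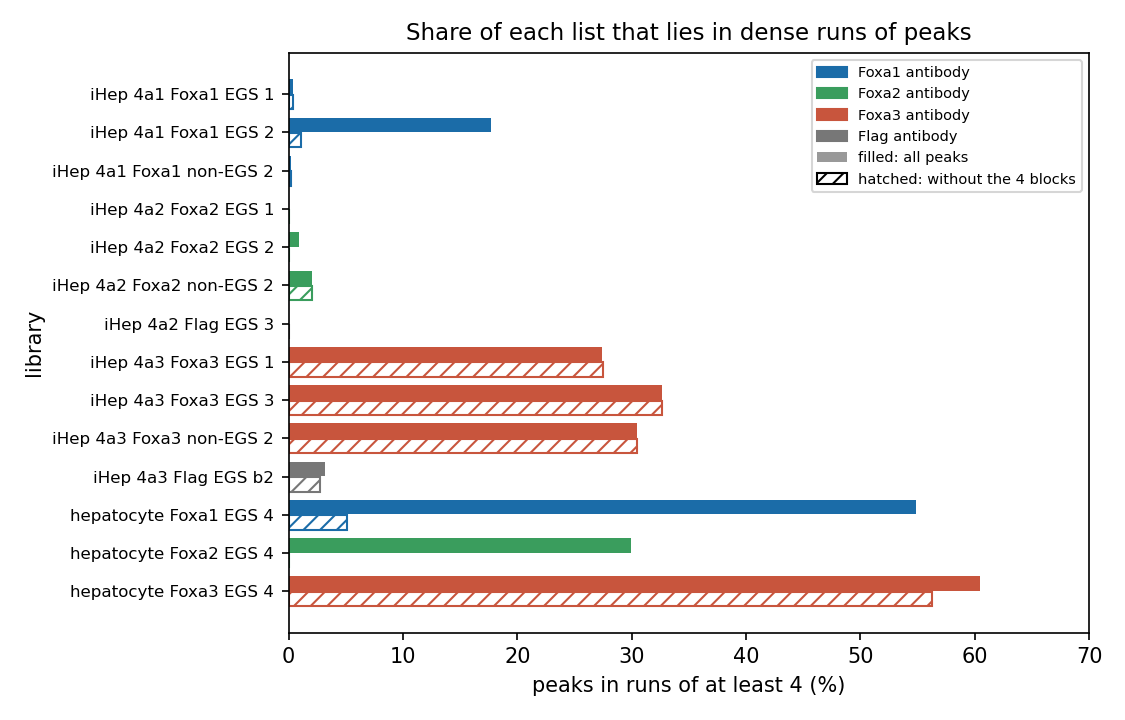
Percent of the peaks of each list that lie in dense runs (at least 4 peaks, gaps of at most 10 kb), 1 pair of bars per library: filled for all peaks, hatched without the 4 dense blocks. Over all peaks the hepatocyte Foxa3 and Foxa1 lists reach 60.5% and 54.8%; without the blocks, which are defined from the hepatocyte lists, the Foxa3 lists keep 27.5% to 56.2% and the other lists at most 5.06%.

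**Figure D4:**
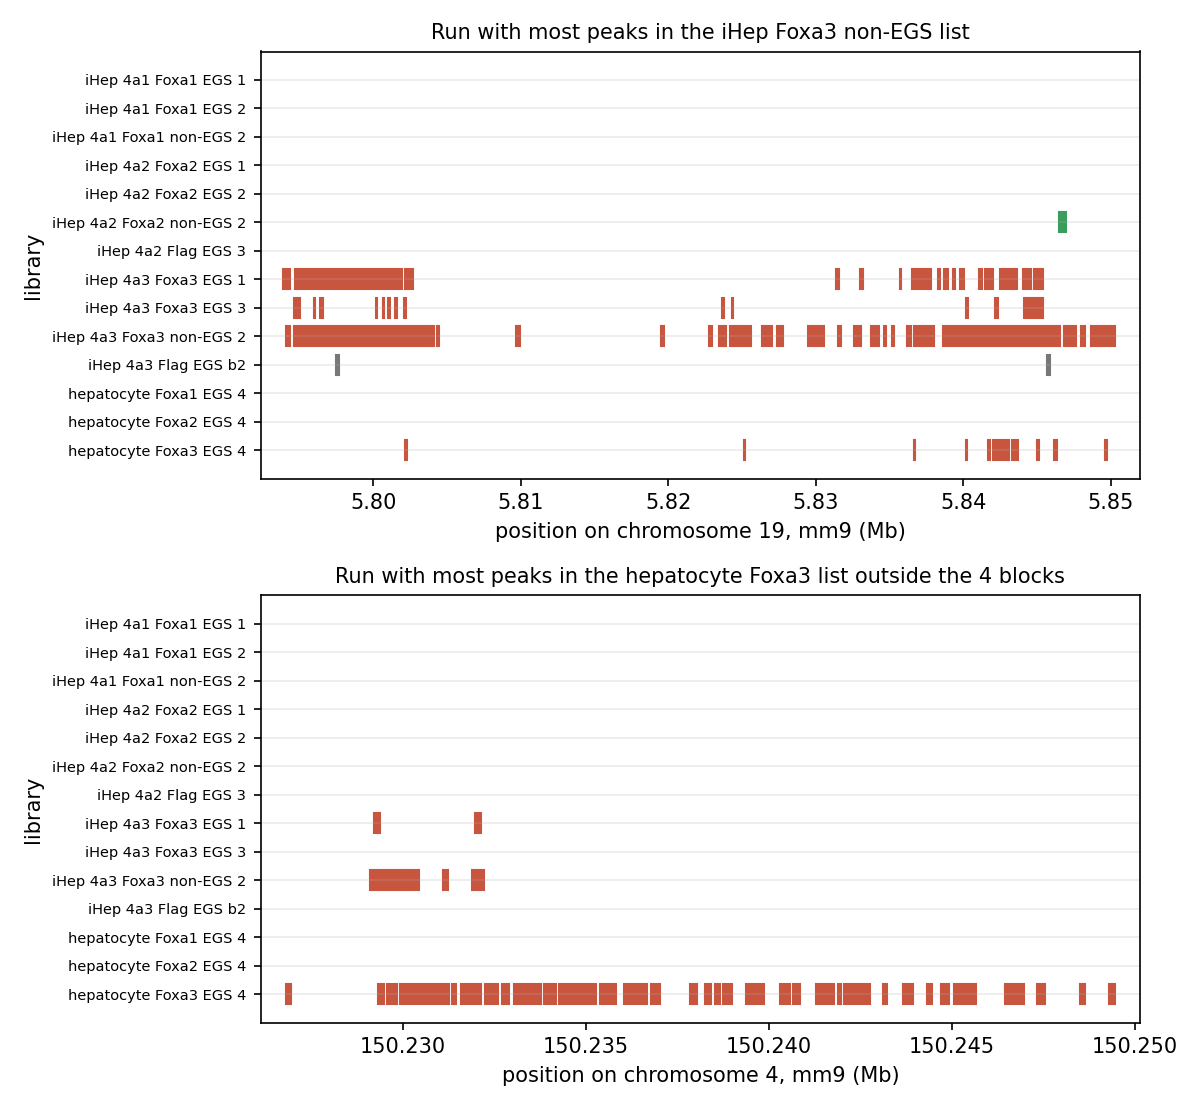
Peaks of each list (boxes, to scale) along the run with most peaks in the iHep Foxa3 non-EGS list, on chromosome 19, and in the hepatocyte Foxa3 list outside the 4 dense blocks, on chromosome 4. Positions are in Mb of mm9. The boxes lie almost entirely in the Foxa3 lists: 35 and 38 peaks in the 2 lists that define the runs.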

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

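The definitions of dense runs and blocks, and all tests of explanations in this part, were chosen after the results were seen, and 4 of the tests were changed after a first outcome.

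Among the 6 EGS Foxa libraries of iHep cells, replicate 3 of line 4a3 stood far below the others with 46 peaks. Its gap to the next on the log10 scale was 0.748 of the range, above Dixon's critical value of 0.625. Among the 6 Foxa1 and Foxa2 lists of iHep cells, EGS replicate 2 of line 4a1 stood out with 17.7% of its peaks in dense runs, a gap of 0.883 of the range. Chance alone marks about 1 in 20 such groups.

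The second of these libraries shares a dense block of peaks with the hepatocyte lists, at the start of chromosome 9 (3000010 to 3038304). It held 79 peaks there, and the hepatocyte lists held 75 (Foxa1), 34 (Foxa2) and 36 (Foxa3), while the other 10 lists held none. Signal that comes with the Foxa1 antibody is argued against as the whole cause, since up to 36 block peaks were found with another antibody and none in the other 2 Foxa1 lists, but a stronger signal with that antibody stays open: block peaks made up 45.2% of the hepatocyte Foxa1 list against 13.9% (Foxa2) and 3.30% (Foxa3), and their median score percentile was 80.4 and 72.9 in the Foxa1 lists that hold them, against 10.2 and 6.55. A sequencing run as the source cannot be told apart: at the share of this library, 9.77 block peaks were expected in the other 2 lists of run code 170 and none was found, but those lists are short, at 46 and 21 peaks, and the test was made stricter after this was seen. Reads from repeated sequence stay a possible explanation that was not tested, as inputs and reads were not used here, and so does a difference in filtering between lists.

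The dense runs of the Foxa3 lists were weighed against 4 explanations. The blocks are argued against as the whole cause in iHep cells, since they held only 4, 0 and 1 peaks of Foxa3 EGS replicates 1 and 3 and the Foxa3 non-EGS list. Leaving them out could therefore hardly lower the difference between Foxa3 and other iHep lists, which was 29.5 percentage points without them. A sequencing run as the whole cause is argued against for Foxa3 EGS replicate 1, at 27.4% (24.9 to 29.9) against 3.17% (2.12 to 4.55) in the Flag list with the same run code (24.2 points, by a test split by run after its first outcomes; the Flag scores are on another scale or threshold), but it cannot be told apart for replicate 3, a list of 46 peaks (14.9 points over the Foxa1 list of run code 170, intervals overlapping, and 31.5 without the blocks), nor for hepatocytes (5.68 points over Foxa1, intervals overlapping, and 30.6 over Foxa2, intervals apart). All these intervals are over peaks, which are not independent within a run, so they are too narrow. The peaks in runs came from 45 runs in Foxa3 EGS replicate 1 and from 5 in the Flag list. Narrow calls that split broad enriched regions stay possible for most of the difference in iHep cells. Merging peaks within 1 kb, without the blocks, left 2.85 points (exact permutation p = 0.17). Broad merged regions, of 2 kb or longer, held 11.9%, 10.9% and 19.3% of the peaks of Foxa3 EGS replicates 1 and 3 and the Foxa3 non-EGS list. In the Foxa1 and Foxa2 lists of iHep cells they held at most 0.67%. Merging joins split calls of 1 region and separate sites within 1 kb alike, so it cannot tell these apart. At 1 place, chosen after its values were seen, a single wide peak stood beside split ones. On chromosome 19 from 5794651 to 5802249, the Foxa3 non-EGS list had 1 peak where Foxa3 EGS replicates 1 and 3 had 6 and 9. Part of the runs in single lists stayed: after merging, the hepatocyte Foxa3 list kept 16.7% of 562 merged peaks in 18 runs, and Foxa3 EGS replicate 1 kept 5.84% of 942. Signal that comes with the Foxa3 antibody and not with the line is also consistent with the tables, as the Flag list of line 4a3 held 2.73% of its peaks in runs without the blocks, against 22.8% and 13.6% in Foxa3 lists limited to as many top-scored peaks, while binding peculiar to Foxa3 itself stays open because the labels do not say which protein carries the tag, and so does signal along highly transcribed genes, since positions relative to genes were not analysed here.

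The Flag list of line 4a3 shared more peaks with the Foxa lists of lines 4a1 and 4a2 than with those of its own line. Longer lists are argued against as the whole cause, by a test that replaced a first version that left this open: among lists of 300 top peaks, the list of the other line shared more Flag peaks in 6 of 6 comparisons, which leave out the Foxa3 list of 46 peaks (paired exact binomial tests over peaks, adjusted p of at most 0.0032). A library of another line under this label cannot be told apart from a true Flag library. Flag peaks fell in 3.22% (1.72 to 5.44) of the 404 regions found in at least 2 Foxa3 lists and no other iHep Foxa list. For each EGS list of the other lines, the regions were defined without that list (404 to 409 regions). Peaks of these lists fell in 0% to 1.22% of them, below the Flag share, but the interval of the highest (0.398 to 2.83) overlaps that of the Flag list. The regions used for the Flag list were thus held to exclusion by more lists. Binding of a tagged protein other than Foxa3 was not tested.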

How the results depend on the processing

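Leaving out the dense blocks, and all settings for dense runs and for the share of one line's regions in another, were chosen after seeing the data. Across the results that answer a comparison, 230 of the alternative values were kept, 16 no longer passed and 5 counts moved further. Kept means the same direction and side of the threshold, or for counts within 1.5 times. None reversed, but shares were scored only against chance overlap, where a reversal was hardly possible. The tally therefore cannot show how far a share moved, nor whether the order of the lines changed. For hepatocyte Foxa2 peaks the order of lines 4a1 and 4a2 did change. The shares were 40.2% and 34.8% with all peaks, and 34.5% and 46.8% without the blocks. Some kept shares moved far. The share of hepatocyte Foxa1 peaks in line 4a1 fell from 52.4% to 1.81% without EGS replicate 2 of that line. That of 4a1 regions in 4a2 fell from 71.3% to 19.6% without the non-EGS library of line 4a2. The ratio of peaks per library was 7.36 with the replicate block (exact p = 0.2, the smallest that block allows) and 9.97 with the line as block; leaving out 1 library gave 6.06 to 12.7, where losing a non-EGS library leaves 0.071 as the smallest exact p. The culture numbers share only a number: between lines 4a1 and 4a2, EGS pairs with the same number shared 41.3% and 34.9% of the shorter list and the others 39.3% and 32.7%. The difference within against between lines was 0.026 on the Jaccard index and 2.15 with EGS libraries only, where 15 labelings cannot pass; leaving out 1 library gave 1.05 to 2.35. Regions common to all 3 lines numbered 178 (top-scoring 50%), 37 (top 300), 130 (EGS only), 218 (non-EGS only) and 191 to 418 (1 library left out); the causes were not tested, except that each uses fewer peaks. The dense-run difference was 2.85 with peaks within 1 kb merged, with or without the blocks, 8.37 with the top 300 peaks, 13.003 with lists thinned to 500 peaks (16.02 and still past the threshold without the blocks, but 4.74 and 7.83 once the unthinned list of 46 peaks was left out), and 25.4 to 29.4 with 1 library left out, where losing a Foxa3 library leaves 0.071 as the smallest exact p. Between 82 and 84 of 91 pairs passed under the alternatives. Of the named regions' library counts, 59 stayed within 1.5 times and 11 moved further under the stricter lists. Gene lists, positions and the forkhead motif were not run. Unknown depth limits every list: a site missing from a short list is not shown to be unoccupied.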

Other observations

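The comparisons in this part were chosen after the data were seen.

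Runs of the Foxa3 lists were partly shared between libraries, of the same line as well as of hepatocytes. Of the 63 runs of the hepatocyte Foxa3 list outside the blocks, 37 held a peak of an iHep Foxa3 list, and 23 (36.5%, 24.7 to 49.6) held no peak of any other list. Examples are chromosome 14 (41917905 to 41940119, 29 peaks), chromosome 5 (90890065 to 90906699, 26 peaks) and chromosome 12 (7988106 to 8026106, 23 peaks). Of the 201 runs of the iHep Foxa3 non-EGS list, 148 (73.6%, 67.0 to 79.6) held no hepatocyte Foxa3 peak, and 101 (50.2%, 43.1 to 57.4) held no peak of Foxa3 EGS replicate 1 of the same line. Counted as runs that meet a run, 10.9% (6.99 to 16.1) met one of the hepatocyte Foxa3 list, 14.9% (10.3 to 20.6) one of Foxa3 EGS replicate 1 and 0.498% one of replicate 3. These shares are bounded by the fewer runs of those lists. In the other direction, 31 of 45 runs of Foxa3 EGS replicate 1 (68.9%, 53.4 to 81.8) met a run of the non-EGS list. So did 2 of 2 runs of replicate 3 and 22 of the 63 hepatocyte runs (34.9%, 23.3 to 48.0). On chromosome 6 (52171874 to 52211547) the Foxa3 non-EGS list had 34 peaks and the other 13 lists had none. On chromosome 12 (55810556 to 55840284) it had 15 peaks, Foxa3 EGS replicate 1 had 14 and the hepatocyte Foxa3 list 13. The hepatocyte Foxa3 peaks in runs and outside runs were found in iHep Foxa3 lists about equally often, at 28.3% (24.6 to 32.3) of 554 and 28.1% (23.9 to 32.5) of 431.

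Flag peaks of line 4a3 were found in 44.5% (39.7 to 49.4) of the 418 regions shared by all 3 lines and in 7.06% (6.07 to 8.16) of the 2394 regions of lines 4a1 and 4a2 that line 4a3 lacked. They were found in 3.22% (1.72 to 5.44) of the 404 regions found in at least 2 Foxa3 lists and no other iHep Foxa list.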
